A study of Danio rerio with 6 samples.

How the data were processed

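Total RNA of whole zebrafish embryos was measured on 6 Agilent 2-colour gene expression arrays. Per the labels, dechorionated embryos were kept from 6 to 48 hours post-fertilization (hpf) at 28 °C in water with 0.1% dimethyl sulfoxide (DMSO), holding either 0.2 µM mITP or none. mITP is the mono-substituted isopropylated triaryl phosphate, a component of commercial flame retardant and plasticiser mixtures. The embryos were wild type or carried the ahr2hu3335 mutation of ahr2, the gene of the main zebrafish aryl hydrocarbon receptor (AHR), a transcription factor that binds planar aromatic ligands. Each of the 3 replicates of a genotype was a pool of at least 9 embryos per treatment, and the labels call them biological replicates. Each array held the treated and the control pool of 1 genotype and replicate in its 2 channels.

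Per the labels, RNA was extracted with RNAzol RT and labelled with Agilent's low-input whole-transcript kit. On the wild-type arrays the mITP RNA carried Cy5 and the DMSO RNA Cy3, and on the mutant arrays the dyes were the other way round. The 3 wild-type arrays lay on 1 slide with 1 scan and the 3 mutant arrays on the other slide with the other scan. Genotype, slide, scan and dye orientation can therefore not be told apart, and no fit with the slide as a block was possible.

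The spot intensity and local background intensity of each channel were deposited as scanner output of Agilent Feature Extraction 10.7.3.1, per the file headers, with flags for spots that were outliers, saturated or well above background. Feature Extraction's own processed intensity was deposited beside them; per the file headers it was background-subtracted, detrended and dye-normalized. The log10 ratio of Cy5 over Cy3 that the authors deposited in the same files served only to find the direction of the authors' value table. That value table held normalized log2 ratios, deposited by the authors with no statement of method, and set against the scanner values it proved to be Cy5 over Cy3 on every array. Its column medians lay between 0.00287 and 0.00478, and its correlation with the log2 ratios computed here was 0.874 on the array of wild-type replicate 1 (slope 1.27) and 0.964 to 0.980 on the others. The submitters' processing notes name Agilent Feature Extraction and limma without a role, and the background correction and normalization behind the value table are not given in the sources used here.

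Mean spot intensities were corrected with the normexp method of limma 3.58.1 (offset 50) in R 4.3.3 with the data.table package (version 1.17.8), and log ratios were normalized within each array by loess with weight 0 for control spots. Of 45220 spots, 43803 measured genes through 43603 probes. Repeated spots of a probe were averaged, and 8 probes whose spots were all outliers on an array were left out. A probe was kept where it was well above background in at least 1 channel on all 3 arrays of at least 1 genotype, which left 32696 probes. The probe with the highest mean intensity stood for a gene, giving 19225 genes, 8369 of them with more than 1 tested probe. Probes were named through the accession in the file and a gene table of the assembly GRCz12tu, used for names only (25854 probes), through a current symbol (4736) or an older symbol (887), and otherwise kept the file's name (12126). Positions are those of the file's annotation on Zv9 (danRer7). Between 69.3% and 73.4% of gene spots were well above background in Cy3 and 72.6% to 76.8% in Cy5, no gene spot was saturated (0 on each array), and 6 to 11 spots per array were outliers. The number of arrays limits the precision.

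Ratios were turned to mITP over DMSO. One limma model (lmFit, eBayes) over all 6 arrays held a mean per genotype, so that both genotypes shared 1 estimate of the spread with 4 residual degrees of freedom. From it came the wild-type response, the mutant response, their average and their difference, each two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. No genotype had both dye orientations, so a dye effect of a probe stays in each single-genotype response, cancels in the average and counts double in the difference. The genotype difference was tested with limma on the mean log2 intensity of both channels per array, quantile normalized between arrays. This mean holds both treatments and both dyes on every array. Log2 levels of a channel are given after loess and this quantile step. Folds are on the scale after the offset, which understates the change of dim genes. A gene with every probe below background on all 3 arrays of a group has only a bound, given as "at least": the mean of the brighter group over that of the dim group, each dim value raised to the lowest signal among probes well above background on that array where it was lower.

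The lists for 25 pathways, tissues and cell types were tested with limma's camera (preset correlation 0.01), adjusted over lists within a comparison. They covered AHR targets, AHR pathway components, cytochrome P450 and conjugation genes under the pregnane X receptor (PXR), the NRF2 antioxidant response, heat shock and unfolded protein response, hypoxia, the circadian clock, p53 and apoptosis, the cell cycle, fatty acid oxidation, sterol synthesis, the retinoic acid pathway and vitellogenins. They also covered cardiac muscle, skeletal muscle, erythroid cells, endothelium, leukocytes, lens crystallins, photoreceptors with the retinal pigment epithelium, neurons and glia, cartilage, liver, exocrine pancreas and gut, and pigment cells. Calls of genes in both genotypes were compared with Fisher's exact test.

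The genes named follow a rule. For each comparison these were, among called genes with a gene symbol, the same sign on every array concerned or no overlap between genotypes, the 10 with the largest increase and the 10 with the largest decrease. To these were added up to 4 members of each list with the smallest p, and always cyp1a, cyp1b1, cyp1c1, cyp1c2, ahrra, ahrrb, tiparp and ahr2. A gene named for 1 comparison may have its values given in the others. Groups, tests, lists, the rule and the alternatives were fixed before the data were examined, except where stated. The alternatives were other background corrections, median centring in place of loess, Feature Extraction's processed intensities, the authors' value table, other filters on dim probes, other rules for several probes of a gene, array weights, the replicate number as a block, scaling between arrays, a 2-fold minimum, the DMSO channels alone, other list tests and leaving out each array.

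The fits were tested on simulated data with 200 genes per comparison changed by 0.5 or 1 on the log2 scale among 19225, and 200 genes with a dye effect of 0.5 alone. At 0.5, 100% of the changed genes were recovered in the wild-type response, 98% in the mutant response, 100% in the average, 87% in the difference and 89% in the genotype difference. Of the genes with a dye effect alone, 198 were called in the wild-type response, 199 in the mutant response, 1 in the average, 200 in the difference and 0 in the genotype difference, all by limma. Where these are not counted as false in the wild-type response, the mutant response and the difference, 5.90% (average) to 8.25% (genotype difference) of all genes called were false. A simulated list shifted by 0.2 was called by camera in the average response, and 0 other lists of 25 were. The simulated genes varied independently of one another, so this does not test list calls among correlated genes. The figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.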

Results

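The arrays compared embryos exposed to 0.2 µM mITP with embryos in 0.1% DMSO alone at 48 hpf, in wild-type fish and in ahr2 mutants, with 3 arrays per genotype and 6 in all. The design asks how the transcriptome of the whole embryo responded to mITP and which part of that response differed in ahr2 mutants. Across 19225 genes the ratios of mITP over DMSO correlated at 0.406 to 0.505 between wild-type arrays and at 0.332 to 0.399 between mutant arrays; these correlations are across genes, which are not independent replicates. Between a wild-type and a mutant array they lay between -0.289 and -0.0201. The dyes were reversed between the genotypes, so a probe that favours 1 dye pushes the ratios of both genotypes apart.

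The probe of ahr2 (Zv9 chromosome 22, 13189275 to 13189334) was read first, since ahr2 is the mutated gene. Its log2 intensity in DMSO was 10.97, 10.68 and 11.01 in wild-type replicates 1 to 3 (mean 10.89 ± 0.18, SD, n = 3) and 9.38, 9.40 and 9.70 in the mutants (9.49 ± 0.18, SD, n = 3). With mITP it was 11.47, 11.39 and 11.78 in wild type (11.55 ± 0.20) and 9.38, 9.39 and 9.64 in the mutants (9.47 ± 0.15). Averaged over both channels ahr2 was 3.33-fold lower in mutants (log2 difference of wild type minus mutant 1.74, SE 0.11, limma adjusted p = 0.000302), and its 4 other probes gave 0.22 to 1.88. The probe reports the amount of transcript, not the function of the receptor, and the position of the mutation relative to it is not given in the sources used here.

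In wild-type embryos mITP raised the genes that the AHR is known to switch on. cyp1a, the cytochrome P450 most used as a marker of AHR activity, rose 14.5-fold (log2 change 3.86 ± 1.73, SD, n = 3). cyp1c1 rose 13.3-fold (3.73 ± 0.46), ahrra, a repressor that feeds back on the AHR, 11.4-fold (3.52 ± 0.21), cyp1c2 9.06-fold (3.18 ± 0.44) and cyp1b1 3.57-fold (1.84 ± 0.17). The largest decreases were in hox genes, which pattern the body axis, and in genes of retinoid handling. hoxb5b fell 3.27-fold (log2 change -1.71 ± 0.28), cyp26a1, the enzyme that degrades retinoic acid, 2.86-fold (-1.52 ± 0.27), and hoxb6b 2.26-fold (-1.18 ± 0.22).

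The limma adjusted p was 0.00371 for cyp1a, 1.17e-05 for cyp1c1 and ahrra, 4.56e-05 for cyp1c2 and 0.000528 for cyp1b1, and each rose on all 3 wild-type arrays. The cyp1a probe lies at Zv9 chromosome 18, 4985480 to 4985539, and the ahrra probe at chromosome 24, 43874504 to 43874563. The wide SD of cyp1a came with its DMSO channel, where the log2 intensity was 9.70, 10.47 and 12.99 in the 3 replicates, against 15.16, 14.56 and 15.02 with mITP. Its log2 change was 3.06 without wild-type replicate 1 and 4.78 without wild-type replicate 3. Other genes with large increases were ccl27a, a chemokine (1.35 ± 0.54), the cathepsins ctsl.1 (1.29 ± 0.18) and ctss2.1 (1.24 ± 0.48), wfikkn1 (1.29 ± 0.67) and sult6b1, a sulfotransferase (1.05 ± 0.07). The 2 other probes of wfikkn1 gave log2 changes of only 0.03 and 0.13. ahr2 itself rose 1.58-fold (0.66 ± 0.14, limma adjusted p = 0.000781) and tiparp, another feedback gene of the AHR, rose by 0.49 ± 0.33 (limma adjusted p = 0.0386). ahrrb, the second AHR repressor, rose at least 1.59-fold, as it was not well above background in DMSO (limma adjusted p = 0.00248). Of the 19 measured AHR targets 11 rose and 1 fell, and 15 passed adjusted over the list alone, 13 of them higher (camera adjusted p = 7.51e-09). The call of the list was lost with an estimated correlation (adjusted p = 0.0996 with an estimated correlation). The 1 that fell was sox9b, a regulator of cartilage and heart development (-0.30), chosen after its values were seen.

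**Figure D1:**
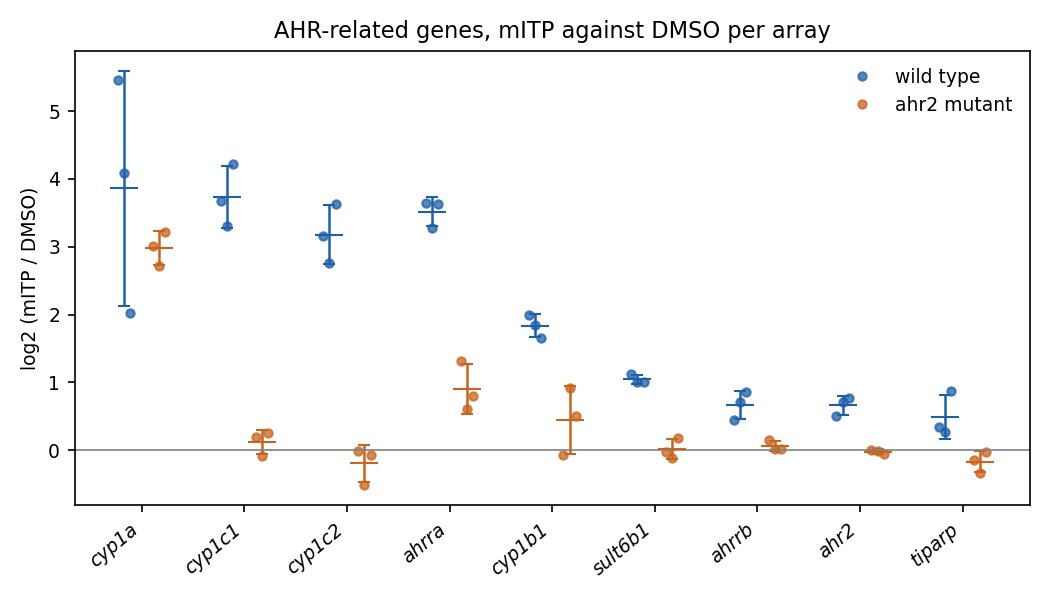
Log2 ratio of mITP over DMSO for 9 AHR-related genes on each array (points), with the mean and SD of the 3 arrays of a genotype (bars). The wild-type values of cyp1c1 (3.31 to 4.22) and cyp1c2 (2.76 to 3.63) lay above those in mutants (-0.09 to 0.25 and -0.51 to -0.01), while cyp1a was higher in both genotypes (means 3.86 and 2.98).

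Further decreases in wild type were in rbp2b, a cellular retinol-binding protein (-1.43 ± 0.45; its other probe -0.15), hoxc1a (-1.06 ± 0.32), hoxb5a (-0.93 ± 0.11), hoxb6a (-0.76 ± 0.09), apcs, a pentraxin of the acute phase (-1.09 ± 0.25; its other probe 0.07), cyp2aa3 (-0.79 ± 0.25) and rho, the rod opsin (-0.94 ± 0.48). Their limma adjusted p lay between 0.000204 (hoxb5a) and 0.0356 (cyp2aa3). The hoxb5b probe lies at Zv9 chromosome 12, 28702673 to 28702732, and that of cyp26a1 at chromosome 12, 9709075 to 9709134.

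Of 58 measured cell cycle genes 19 fell and 1 rose in wild type, and 38 passed adjusted over the list alone, 36 of them lower (median log2 change -0.28, camera adjusted p = 7.93e-17; adjusted p = 0.643 with an estimated correlation). Among them were pcna, the replication clamp (-0.60 ± 0.06), the helicase subunits mcm4 (-0.53 ± 0.12) and mcm3 (-0.43 ± 0.11), and the primase prim1 (-0.49 ± 0.09). Genes of fatty acid oxidation were lower (0 of 39 higher, 4 lower, 10 adjusted over the list alone, 9 of them lower, camera adjusted p = 0.00062; adjusted p = 0.643 with an estimated correlation), among them decr1 (-0.37 ± 0.05) and hadhab (-0.35 ± 0.16). Liver and plasma protein genes were lower as well (0 of 37 higher, 9 lower, 15 adjusted over the list alone, 11 of them lower, camera adjusted p = 0.00496; adjusted p = 0.643 with an estimated correlation), with apoa4a, an apolipoprotein (-0.70 ± 0.41), the iron carrier tfa (-0.69 ± 0.50) and cp, which encodes ceruloplasmin (-0.56 ± 0.25).

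Lens crystallins were higher in wild type (14 of 57 higher, 0 lower, 17 adjusted over the list alone, camera adjusted p = 0.00279; adjusted p = 0.718 with an estimated correlation). Without wild-type replicate 1 the list did not pass (adjusted p = 0.321). crygs1 rose by 0.92 ± 0.30 and crygm2d3 by 0.69 ± 0.23. Genes of the NRF2 antioxidant response were higher (5 of 34 higher, 0 lower, 9 adjusted over the list alone, 8 of them higher, camera adjusted p = 0.0166; adjusted p = 0.643 with an estimated correlation). Its leading members abcc2, an efflux pump (0.60 ± 0.08), and keap1b, which holds NRF2 in check (0.57 ± 0.23), were both read by probes with a run of alternating G and T bases, a probe type that was brighter in Cy5 in both genotypes. The p53 and apoptosis list was higher with 1 of 30 genes called, bcl2l1, which restrains cell death (0.28 ± 0.11), and 5 adjusted over the list alone (camera adjusted p = 0.0149; adjusted p = 0.643 with an estimated correlation). The hypoxia list was higher (4 of 45 higher, 0 lower, 6 adjusted over the list alone, 5 of them higher, camera adjusted p = 0.0352; adjusted p = 0.805 with an estimated correlation), with igfbp1a, which binds insulin-like growth factors (0.54 ± 0.06), and the glucose transporter slc2a3a (0.53 ± 0.16; its other probe -0.01). The sterol synthesis list was higher with 1 of 24 genes called, the prenyl transferase gene fdps (0.51 ± 0.04), and 1 adjusted over the list alone (camera adjusted p = 0.0451; adjusted p = 0.718 with an estimated correlation). Leaving out 1 array ended the other 4 calls as well. Without wild-type replicate 2 the adjusted p was 0.0923 for NRF2, 0.126 for p53, 0.0748 for hypoxia and 0.611 for sterol synthesis. Without wild-type replicate 3 it was 0.442 for hypoxia. The sterol list also did not pass without mutant replicate 2 (0.0555) or 3 (0.0522). The other 16 lists did not pass (camera adjusted p from 0.0668 to 0.910); in 3 of these, cardiac muscle, heat shock and PXR, the median, mean and test differed in sign.

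In all, limma called 1147 of 19225 genes in the wild-type response, 657 higher and 490 lower, and 18 of them changed at least 2-fold. All wild-type arrays carried mITP in Cy5, and 110 of the called genes, all of them higher, were on probes with a run of alternating G and T. With median centring in place of loess limma called 0 genes (233 at an unadjusted p under 0.05, against 4462 after loess), and without 1 array it called 289 (wild-type replicate 3), 456 (wild-type replicate 2), 623 (mutant replicate 3) or 646 (mutant replicate 1).

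In ahr2 mutants 2 AHR targets still rose. cyp1a rose 7.88-fold (log2 change 2.98 ± 0.25, SD, n = 3) and ahrra 1.87-fold (0.90 ± 0.37). The strongest decreases were in rho, which fell 4.91-fold (-2.30 ± 0.46), hoxb5b, which fell 2.62-fold (-1.39 ± 0.14), and hoxb6b, 2.33-fold (-1.22 ± 0.13). Of other genes that had fallen in wild type too, hoxb5a fell 1.73-fold (-0.79 ± 0.06) and cyp26a1 1.83-fold (-0.87 ± 0.35).

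The limma adjusted p in mutants was 0.0229 for cyp1a, 0.0112 for ahrra, 0.00269 for rho, 0.0022 for hoxb5b, hoxb6b and hoxb5a, and 0.0163 for cyp26a1, and each gene had the same sign on all 3 mutant arrays. The call of cyp1a was lost without any 1 of the mutant arrays, at log2 changes of 2.86 to 3.11, and that of ahrra without replicate 3. Both genotypes shared 1 estimate of the spread, which for cyp1a held the scatter of the wild-type DMSO channel (SD 1.72, against 0.11 in mutant DMSO). The lost calls of cyp1a therefore do not by themselves show scatter among the mutant arrays. The other AHR-related genes did not pass in mutants: the log2 change was 0.45 ± 0.50 for cyp1b1 (limma adjusted p = 0.182), 0.12 ± 0.18 for cyp1c1 (0.705), -0.20 ± 0.27 for cyp1c2 (0.532), -0.17 ± 0.15 for tiparp (0.457) and -0.02 ± 0.03 for ahr2 (0.889). ahrrb was not well above background in mutants with either treatment. Of the 19 AHR targets 2 rose and 0 fell, with 3 adjusted over the list alone (camera adjusted p = 0.199).

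Of 42 measured genes of the photoreceptors, the light-sensing cells of the retina, and of the pigment epithelium beside them (together, photoreceptor genes), 5 fell and 0 rose in mutants, and 18 passed adjusted over the list alone (median -0.27, camera adjusted p = 7.19e-10; adjusted p = 0.812 with an estimated correlation). Beside rho, at Zv9 chromosome 8, 55706890 to 55706949, they were sagb, a rod arrestin (-0.89 ± 0.20), gngt1, a transducin subunit (-0.78 ± 0.41), rom1b (-0.53 ± 0.17) and rom1a, a disc membrane protein, which fell by at least 0.59 on the log2 scale as it was not well above background with mITP. Lens crystallins were lower in mutants (0 of 57 higher, 8 lower, 19 adjusted over the list alone, 18 of them lower, camera adjusted p = 3.74e-05; adjusted p = 0.812 with an estimated correlation), with crygm2d4 at -0.60 ± 0.21 and crygm2d3 at -0.55 ± 0.17. As the same list was higher in wild type, the list median was on the side of Cy5 in both genotypes. Of 33 retinoic acid pathway genes 5 fell and 0 rose, with 6 adjusted over the list alone, but the list did not pass (camera adjusted p = 0.199). Among them dhrs3b, which reduces retinal to retinol, fell by 0.81 ± 0.19 on the log2 scale. Cell cycle genes gave 0 calls of 58 in either direction and 0 adjusted over the list alone (camera adjusted p = 0.197). The remaining lists did not pass either, and of the 23 that did not pass the adjusted p ran from 0.197 to 0.937; in cardiac muscle, leukocytes and pigment cells the median, mean and test differed in sign.

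Single genes outside these groups changed modestly in mutants. The largest increases after cyp1a and ahrra were in fbxo2 (0.57 ± 0.10), ndufaf6 (0.56 ± 0.31), mrps10 (0.54 ± 0.18), pygl, which releases glucose from liver glycogen (0.53 ± 0.12), col14a1 (0.52 ± 0.27), usp5 (0.46 ± 0.06), olfml3a (0.45 ± 0.13) and rpe (0.43 ± 0.18), at limma adjusted p from 0.00361 to 0.0473. Further decreases were in neu3.2, a sialidase (-0.74 ± 0.20), and mrpl20 (-0.72 ± 0.03), the latter on a probe with a run of alternating G and T. limma called 313 genes in all, 36 higher and 277 lower, 4 of them at least 2-fold. mITP was in Cy3 on every mutant array and 92 of the lower genes were on such probes. With median centring in place of loess limma called 0 genes (870 at an unadjusted p under 0.05, against 3474 after loess), and without 1 mutant array it called 80 (replicate 1), 84 (replicate 2) or 36 (replicate 3).

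The average of both genotypes is the response in which a dye effect cancels. Among the genes with the largest changes there were AHR targets, 2 hox genes, a retinoid enzyme and the rod opsin. cyp1a rose by a log2 change of 3.42 (SE 0.34), ahrra 4.62-fold (2.21, SE 0.089), cyp1c1 3.80-fold (1.93, SE 0.10), cyp1c2 2.81-fold (1.49, SE 0.11) and cyp1b1 2.21-fold (1.14, SE 0.11). rho fell 3.07-fold (-1.62, SE 0.13), hoxb5b 2.93-fold (-1.55, SE 0.070), hoxb6b 2.29-fold (-1.20, SE 0.060) and cyp26a1 2.29-fold (-1.19, SE 0.092), each on all 6 arrays.

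The limma adjusted p of the average was 0.00363 for cyp1a, 3.51e-05 for ahrra, 7.17e-05 for cyp1c1, 0.000571 for cyp1c2, 0.00247 for cyp1b1, 0.00105 for rho, 4.61e-05 for hoxb5b, 5.92e-05 for hoxb6b and 0.000884 for cyp26a1. For cyp1c1, cyp1c2 and cyp1b1, as for sult6b1, ugt1a1, ahr2, rbp2b, fdps, ctsl.1, ccn2b and slc43a2b, the average combines a change in wild type with a mutant value that did not pass. Of 19 AHR targets 8 rose and 0 fell, with 10 adjusted over the list alone, 9 of them higher (camera adjusted p = 6.35e-12; adjusted p = 0.0535 with an estimated correlation). sult6b1 rose by 0.53 and ugt1a1, which conjugates bilirubin and foreign compounds, by 0.33, while tiparp at 0.16 did not pass (limma adjusted p = 0.442). ahr2 rose by 0.32 in the average, as 1 of the 9 AHR pathway components and the 1 passing adjusted over the list alone (camera adjusted p = 0.697). Of 33 retinoic acid pathway genes 3 fell and 0 rose, with 12 adjusted over the list alone, 9 of them lower (camera adjusted p = 0.00778; adjusted p = 0.423 with an estimated correlation): cyp26a1, dhrs3b (-0.74, SE 0.052) and dhrs3a (-0.60, SE 0.080), the last well above background with mITP on 2 of 3 arrays of each genotype. The further hox genes hoxb5a (-0.86, SE 0.041) and hoxc1a (-0.85, SE 0.080) fell, as did rbp2b (-1.16, SE 0.18; its other probe -0.11) and apcs (-0.84, SE 0.079; its other probe -0.09). Photoreceptor genes were lower (0 of 42 higher, 5 lower, 18 adjusted over the list alone, 17 of them lower, camera adjusted p = 7.78e-11; adjusted p = 0.423 with an estimated correlation), with sagb at -0.70, gngt1 at -0.66 and rom1b at -0.44.

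**Figure D2:**
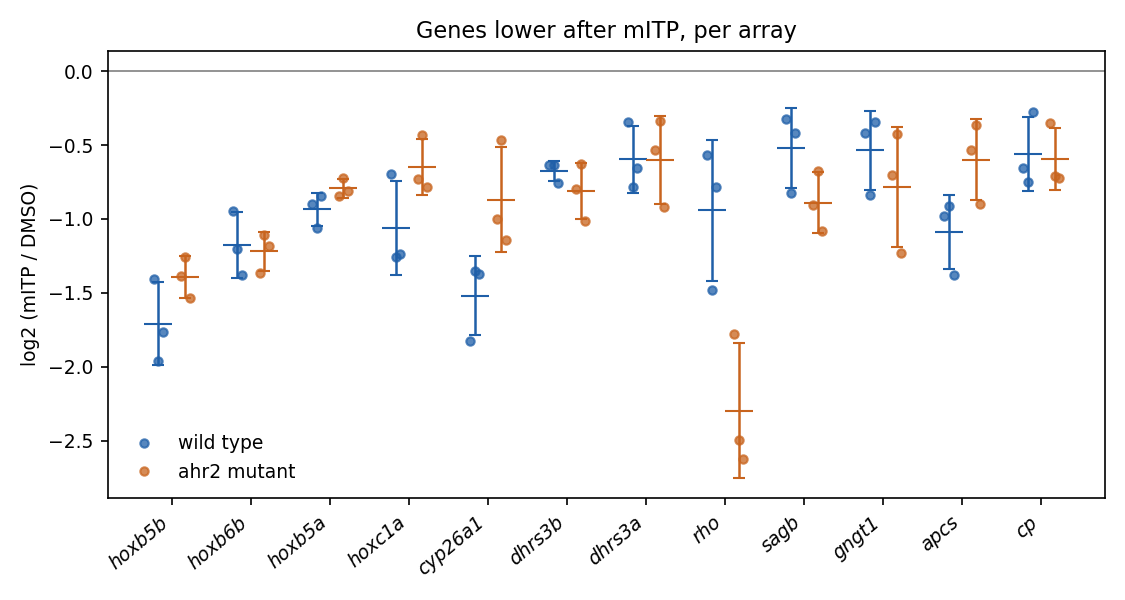
Log2 ratio of mITP over DMSO for 12 genes that fell in the average response, on each array (points), with the mean and SD of the 3 arrays of a genotype (bars). hoxb5b (-1.71 in wild type and -1.39 in mutants) and hoxb6b (-1.18 and -1.22) lay below 0 on all 6 arrays, and rho lay lower in mutants (-2.30) than in wild type (-0.94).

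Cell cycle genes were lower in the average as a list (camera adjusted p = 7.85e-12, and 0.560 with an estimated correlation). Of 58 genes 0 were called by limma over all genes and 8 adjusted over the list alone. The list median was -0.28 in wild type but 0.03 in mutants, where the list did not pass. Its average thus combines a decrease in wild type with no decrease in mutants. Fatty acid oxidation genes were lower (0 of 39 called, 3 adjusted over the list alone, camera adjusted p = 0.00026), and the NRF2 list (0 of 34 called, 6 adjusted over the list alone, camera adjusted p = 0.000222) and the p53 list (0 of 30 called, 0 adjusted over the list alone, camera adjusted p = 0.00249) were higher; all 3 had adjusted p = 0.423 with an estimated correlation. The NRF2 and p53 lists changed direction, without a call, with median centring (adjusted p = 0.572 and 0.912). Sterol synthesis was higher with 1 of 24 genes called, fdps (0.30), and 1 adjusted over the list alone (camera adjusted p = 0.00306; adjusted p = 0.560 with an estimated correlation), and did not pass without wild-type replicate 2 (adjusted p = 0.143). The lens crystallins, which had moved in opposite directions in the genotypes, had 0 of 57 genes called and 0 adjusted over the list alone in the average (camera adjusted p = 0.915).

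The other lists did not pass in the average, and of each the genes called by limma and those adjusted over the list alone were few. Leukocyte genes (camera adjusted p = 0.0659) had 1 of 34 higher and 2 lower, with 6 adjusted over the list alone, 4 of them higher, and liver genes (0.138) had 1 of 37 lower, cp at -0.58, with 5, 4 of them lower. The numbers adjusted over the list alone that follow count both directions. Skeletal muscle (0.310) had 1 of 54 lower with 1 adjusted over the list alone, pigment cells (0.749) 1 of 29 higher with 2, neurons and glia (0.761) 1 of 43 lower with 1, cardiac muscle (0.915) 1 of 37 lower with 3, cartilage (0.915) 2 of 36 lower with 5, and PXR with its conjugation genes (0.915) 1 of 34 higher with 2. Hypoxia (0.386; 45 genes) had 0 called and 2 adjusted over the list alone, and exocrine pancreas and gut (0.408; 19 genes) 0 and 1. Erythroid genes (0.285; 25 genes), the circadian clock (0.627; 37 genes), vitellogenins (0.749; 6 genes), endothelium (0.915; 30 genes) and heat shock (0.915; 41 genes) had 0 by either count. The median, mean and test differed in sign for AHR pathway components, cartilage, heat shock, hypoxia and pigment cells.

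**Figure D3:**
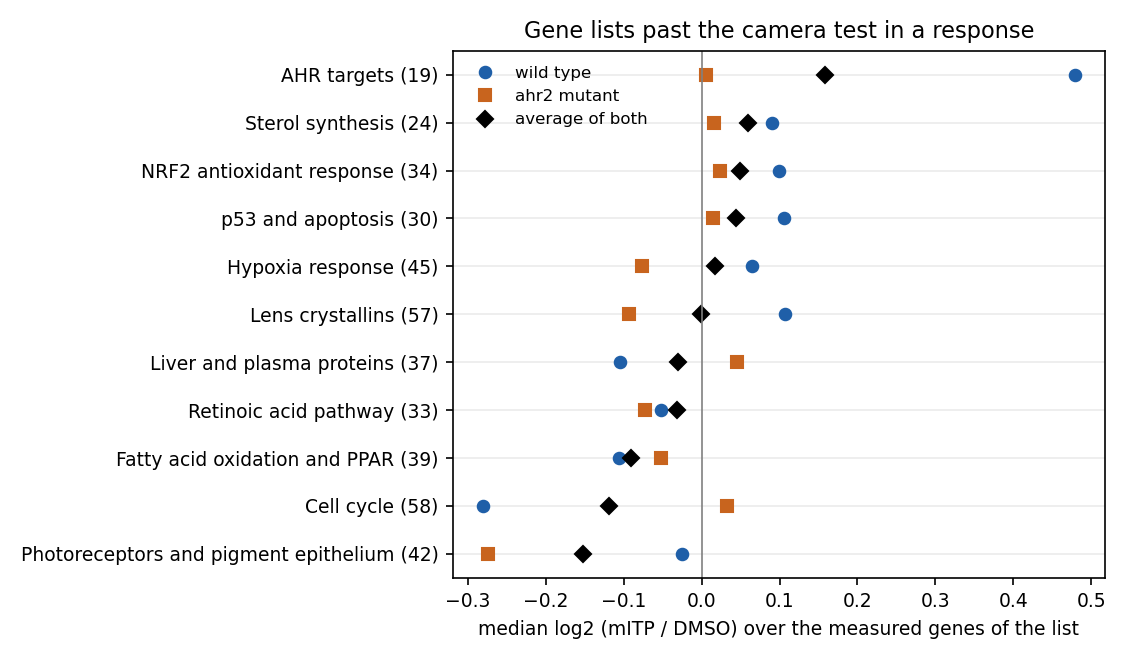
Median log2 ratio of mITP over DMSO over the measured genes of each list that passed camera in the wild-type, mutant or average response (x axis; number of measured genes in brackets). Photoreceptor genes lay at -0.025 in wild type, -0.27 in mutants and -0.15 in the average, and lens crystallins at 0.11 in wild type and -0.09 in mutants.

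Among single genes of the average, ctsl.1 rose by 0.67 (limma adjusted p = 0.000584), ccn2b, a secreted growth regulator, by 0.53 (0.0185), pygl by 0.51 (0.014), slc43a2b, an amino acid transporter, by 0.44 (0.0299) and mrps10 by 0.40 (0.0307). limma called 84 genes in all, 32 higher and 52 lower, 10 of them at least 2-fold and 0 on probes with a run of alternating G and T. With median centring it called 5 genes, cyp1a, ahrra, hoxb5b, hoxb6b and hoxc1a, and without 1 mutant array it called 30 (replicate 1), 46 (replicate 2) or 29 (replicate 3).

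The difference in response asks which genes answered mITP differently in the 2 genotypes. The 3 largest differences were in AHR genes whose rise was larger in wild type: cyp1c1 by 3.61 on the log2 scale (12.2-fold, SE 0.20), cyp1c2 by 3.38 (10.4-fold, SE 0.21) and ahrra by 2.62 (6.13-fold, SE 0.18). For cyp1b1 the difference was 1.39 (2.62-fold, SE 0.22). cyp1a was not called: its difference of 0.88 had an SE of 0.68 (limma adjusted p = 0.450). Without the array of wild-type replicate 3 it was 1.80 and passed, and without that of wild-type replicate 1 it was 0.08.

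The limma adjusted p of the difference was 8.65e-05 for cyp1c1 and cyp1c2, 9.92e-05 for ahrra and 0.00839 for cyp1b1, and the 3 wild-type values lay above the 3 mutant values for each. The difference was 1.03 for sult6b1, 0.68 for ahr2 and 0.66 for tiparp. Of 19 AHR targets 8 were higher and 0 lower, with 10 adjusted over the list alone, 9 of them higher (camera adjusted p = 5.67e-05; adjusted p = 0.309 with an estimated correlation). Of 58 cell cycle genes 15 were lower and 1 higher, with 30 adjusted over the list alone, 27 of them lower (camera adjusted p = 8.34e-12; adjusted p = 0.903 with an estimated correlation), among them pcna (-0.84), mcm4 (-0.68) and tyms, which makes thymidylate (-0.61). Lens crystallins were higher (16 of 57 higher, 0 lower, 23 adjusted over the list alone, 20 of them higher, camera adjusted p = 5.67e-05; adjusted p = 0.903 with an estimated correlation), with crygs1 at 1.36 and crygm2d3 at 1.24. The photoreceptor list was higher (1 of 42 higher, 1 adjusted over the list alone, camera adjusted p = 0.00994; adjusted p = 0.903 with an estimated correlation), with rho at 1.35. It had passed in mutants and not in wild type (camera adjusted p = 0.0668). Liver genes were lower (1 of 37 higher, 3 lower, 8 adjusted over the list alone, 7 of them lower, camera adjusted p = 0.0111; adjusted p = 0.903 with an estimated correlation), with apoa4a at -0.84. With median centring the list changed direction without passing (adjusted p = 0.626). Hypoxia genes were higher (7 of 45 higher, 0 lower, 8 adjusted over the list alone, all higher, camera adjusted p = 0.0316; adjusted p = 0.903 with an estimated correlation), with slc2a3a at 0.72 and eno1a, a glycolytic enzyme, at 0.67. The 3 other probes of eno1a gave -0.51 to -0.40. Without 1 array the adjusted p of hypoxia was 0.270 (wild-type replicate 3), 0.101 (mutant replicate 1) or 0.0834 (mutant replicate 2). That of photoreceptors was 0.114 (wild-type replicate 1) or 0.0913 (mutant replicate 3), and that of liver 0.0903 (mutant replicate 1). The other 19 lists did not pass (camera adjusted p from 0.0740 to 0.985), and in cardiac muscle, erythroid, heat shock, retinoic acid and skeletal muscle the median, mean and test differed in sign.

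Other single genes with large differences were ccl27a (1.47), mak16 (-0.97), sumo3b (-0.79), got1 (-0.77), col14a1 (-0.77), usp5 (-0.77), pcca (-0.76), sparc, a matrix glycoprotein (-0.76), and slbp, which binds histone messages (-0.75), all by limma. pde6hb (1.68), mrpl20 (1.54), parn (1.46), acot9.2 (1.36) and mybpc2b (1.24) were read by probes with a run of alternating G and T. limma called 1533 genes, 1010 higher and 523 lower in wild type, 98 of them at least 2-fold. Each wild-type array had mITP in Cy5 and each mutant array in Cy3, so genotype and dye orientation cannot be told apart here, and 121 of the higher calls were on such repeat probes. With median centring limma called 0 genes (505 at an unadjusted p under 0.05, against 5081 after loess), and without 1 array it called 836 (wild-type replicate 2), 653 (wild-type replicate 3), 753 (mutant replicate 1), 533 (mutant replicate 2) or 422 (mutant replicate 3).

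Set side by side, the responses of the genotypes shared 25 genes called in the same direction and held 166 called in opposite directions. The 3 genes up in both were cyp1a, ahrra and pygl, against 1.23 from independent lists (Fisher's exact test, two-sided, odds ratio 2.58, p = 0.124). That odds ratio ran from 0 to 15.8 when 1 array was left out. The 22 genes down in both, against 7.06 (odds ratio 3.41, Fisher's exact p = 2.74e-06; 7.48 to 20.01 over 6 to 21 genes when 1 array was left out), included hoxb5b, hoxb6b, hoxb5a, hoxc1a, cyp26a1, dhrs3a, dhrs3b, rho, sagb, apcs, cp and gfap, the intermediate filament of glia. Up in wild type and down in mutants were 162 genes, against 9.47 (odds ratio 52.4, Fisher's exact p = 2.23e-168), and the reverse held for 4, against 0.918 (odds ratio 4.81, Fisher's exact p = 0.0129). The last odds ratio ran from 0 to 16.8 when 1 array was left out. Of the 166 genes, 89 were on probes with a run of alternating G and T. At an unadjusted p under 0.05 the odds ratios for genes up in both and down in both fell under 1 (0.440 and 0.462). Both responses come from 1 fit with a shared spread per gene, so their lists of calls are not independent even without a shared response. The Fisher tests also count genes, which are not independent replicates. Across genes, the responses correlated at -0.211 (Pearson) and -0.302 (Spearman).

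**Figure D4:**
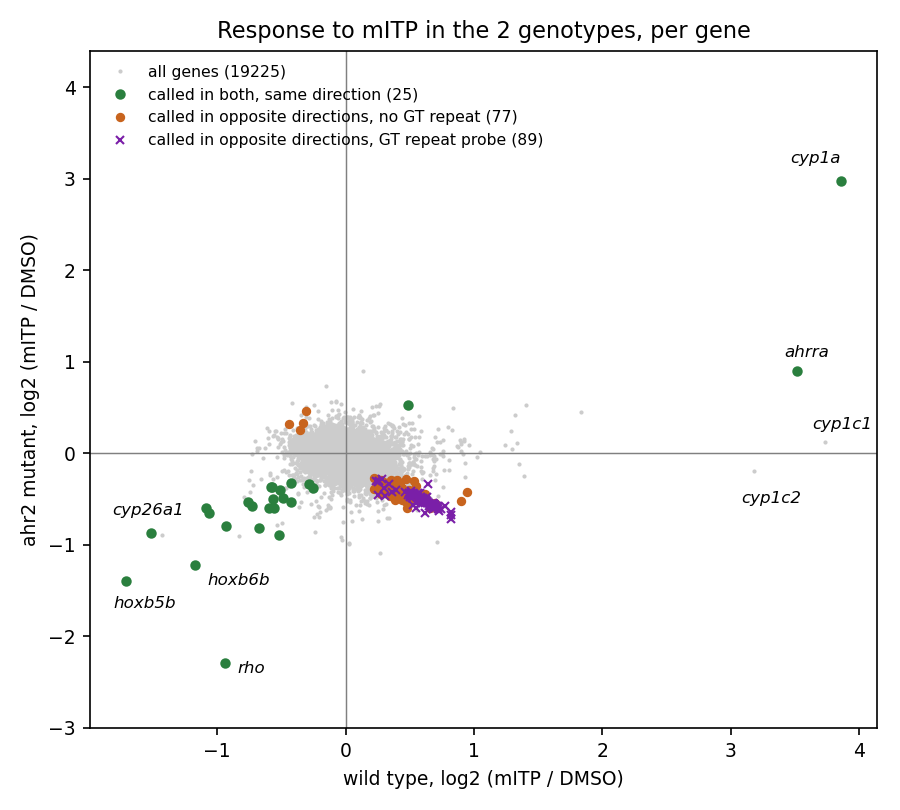
Log2 ratio of mITP over DMSO in wild type (x axis) against ahr2 mutants (y axis), each point a gene of 19225. Genes called in both genotypes are marked as the same direction (25), opposite directions without a GT repeat in the probe (77) and opposite directions on probes with one (89).

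The genotype difference compares wild-type with mutant embryos over both treatments. Beside ahr2, AHR targets were among the genes higher in wild type. cyp1a was 7.49-fold higher (log2 2.91; 12.98 ± 0.89 in wild type against 10.08 ± 0.06 in mutants, SD, n = 3), and in DMSO alone its log2 intensity was 9.70, 10.47 and 12.99 against 8.64, 8.67 and 8.46. cyp1c1 was 4.87-fold, cyp1c2 4.30-fold and ahrra 2.91-fold higher, and cyp1b1 by 1.07 on the log2 scale. With the DMSO channels alone these 4 did not pass, while cyp1a did (log2 difference 2.465, limma adjusted p = 0.0456). DMSO RNA was in Cy3 in wild type and in Cy5 in mutants, so a dye effect of a probe stays in this comparison. The log2 differences of the 4 were 0.48 for cyp1c1 (limma adjusted p = 0.147), 0.42 for cyp1c2 (0.255), 0.24 for ahrra (0.630) and 0.37 for cyp1b1 (0.426). s100t, a calcium-binding protein gene, and rrm2b, a ribonucleotide reductase subunit, were called higher in wild type. In mutants their probes were well above background on only 2 of 3 arrays in DMSO and 1 of 3 with mITP. The other probe of s100t gave a log2 difference of 0.03, and with the DMSO channels alone s100t did not pass (limma adjusted p = 0.154). cyp2aa6 was 3.43-fold higher in wild type. prss59.1, a trypsin-type digestive protease, was 3.12-fold and sult3st4, well above background on 2 of 3 wild-type arrays in DMSO, 2.67-fold higher in mutants.

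The limma adjusted p was 0.00536 for cyp1a, 3.31e-05 for cyp1c1 and s100t, 0.000178 for cyp1c2, 0.00737 for ahrra, 0.0258 for cyp1b1, 0.00152 for rrm2b, 0.000221 for cyp2aa6, 0.00387 for prss59.1 and 0.0132 for sult3st4. tiparp (0.29, limma adjusted p = 0.0578) did not pass. Of 19 AHR targets 8 were higher and 0 lower in wild type, with 13 adjusted over the list alone, 12 of them higher (camera adjusted p = 3.25e-10; adjusted p = 0.328 with an estimated correlation). Further genes higher in wild type were tma7 (2.07; on chromosome 22, like ahr2 and sult3st4) and zfp106 (1.41). Higher in mutants were timeless (-1.51; its other probe 0.11), aga (-1.47), capgb (-1.30; 0.09), ufsp2 (-1.22; 0.14), rnf146 (-1.18; 0.30), uqcc2 (-1.16), bach1b (-1.13) and atp1a3b (-1.12). The second value of a pair is again that of the other probe, and bach1b was well above background with mITP on 2 of 3 wild-type arrays. With the DMSO channels alone ufsp2, uqcc2 and bach1b did not pass (limma adjusted p = 0.0597, 0.0583 and 0.0524).

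The lists of the genotype difference were not tested with the DMSO channels alone. Their values hold the mITP channels too, so a differing response to mITP can enter them. In the difference in response the cell cycle median was -0.31 and the photoreceptor median 0.24, the same signs as in the genotype difference. The liver median there was -0.13, the opposite sign. Stress and liver genes were higher in wild type. The heat shock and unfolded protein list had 6 of 41 genes higher and 2 lower, with 9 adjusted over the list alone, 7 of them higher (camera adjusted p = 0.00139; adjusted p = 0.390 with an estimated correlation); asns, which makes asparagine, was higher by 0.77 and chac1, which degrades glutathione, by 0.68. In the NRF2 list 6 of 34 were higher and 1 lower, with 7 adjusted over the list alone, 6 of them higher (camera adjusted p = 0.00786; adjusted p = 0.551 with an estimated correlation), among them sqstm1, an autophagy receptor (0.87), nfe2l2a, which encodes an NRF2 (0.59), and gstp1.1, at least 1.48-fold higher as it was not well above background in mutants. Liver genes had 3 of 37 higher and 2 lower, with 6 adjusted over the list alone, 4 of them higher (camera adjusted p = 0.00215; adjusted p = 0.432 with an estimated correlation), with apom at 0.98. The p53 list was higher with 1 of 30 genes called, sesn2 (0.69), and 1 adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.475 with an estimated correlation). The circadian list was higher with 1 of 37 called, cry2 (0.43), and 1 adjusted over the list alone (camera adjusted p = 0.0141; adjusted p = 0.604 with an estimated correlation). Photoreceptor genes were higher with 0 of 42 called and 0 adjusted over the list alone (camera adjusted p = 0.000748; adjusted p = 0.673 with an estimated correlation). Cell cycle genes were lower in wild type with 1 of 58 called, cdc20 (-1.11), and 1 adjusted over the list alone (median -0.23, camera adjusted p = 1.85e-07; adjusted p = 0.673 with an estimated correlation). Erythroid genes were lower with 1 of 25 called, slc4a1a, the red cell anion exchanger (-0.47), and 2 adjusted over the list alone (camera adjusted p = 0.00786; adjusted p = 0.328 with an estimated correlation). With the DMSO channels alone cdc20 (-0.71, limma adjusted p = 0.0689), slc4a1a (-0.34, 0.190) and cry2 (0.33, 0.302), the only called genes of their lists, did not pass. In that comparison asns, chac1, sqstm1, nfe2l2a, gstp1.1, apom and sesn2 passed. Without mutant replicate 2 the circadian (adjusted p = 0.338) and photoreceptor lists (0.0723) did not pass, nor did p53 without wild-type replicate 2 (0.0613). The other 16 lists did not pass (camera adjusted p from 0.0561 to 0.840); AHR pathway components, exocrine pancreas, leukocytes, neurons and PXR had a median, mean and test of differing sign.

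limma called 780 genes between the genotypes, 404 higher and 376 lower in wild type, 87 of them at least 2-fold. Each genotype lay on its own slide with its own scan, so genotype and slide cannot be told apart, and 83 of the 678 genes placed on chromosome 22 were called (12.2%, against 3.69% of those placed elsewhere). With median centring in place of quantile normalization limma called 72 genes, 18.1% of them higher against 51.8%, and without 1 array it called 325 (wild-type replicate 2), 215 (mutant replicate 1) or 242 (mutant replicate 3).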

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

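The test of GT repeats, the test on probes without such a repeat and the 3 tests on the cyp1a channel were chosen only after the result was seen; the others in this part were not.

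limma's test of the difference between the genotypes passed for 1533 genes, and the ratio of each gene below differed by that test (log2, wild type minus mutant). A dye effect of the probe stays in this difference, so a call need not be a differing response to mITP. Among AHR genes the difference was 3.61 for cyp1c1, 3.38 for cyp1c2, 2.62 for ahrra, 1.39 for cyp1b1, 1.03 for sult6b1, 0.68 for ahr2 and 0.66 for tiparp. On probes with a run of at least 10 alternating G and T bases it was 1.68 for pde6hb, 1.54 for mrpl20, 1.46 for parn, 1.36 for acot9.2, 1.24 for mybpc2b, 1.13 for abcc2 and 1.00 for keap1b. Among crystallins it was 1.36 for crygs1, 1.24 for crygm2d3, whose other probe gave 1.00, and 1.08 for crygm2d4. rho fell further in mutants, by 1.35. Other genes higher in the wild-type response were ccl27a (1.47), ctsl.1 (1.25), ctss2.1 (1.15), neu3.2 (0.99), ccn2b (0.79), slc2a3a (0.72), igfbp1a (0.60), slc43a2b (0.52), fdps (0.43) and sesn2 (0.41). eno1a gave 0.67 on the probe used but -0.51 to -0.40 on its 3 other probes. pcna (-0.84), slbp (-0.75), mcm4 (-0.68), tyms (-0.61), prim1 (-0.51) and mcm3 (-0.50) were lower. So were mak16 (-0.97), apoa4a (-0.84), sumo3b (-0.79), got1 (-0.77), col14a1 (-0.77), usp5 (-0.77), pcca (-0.76), sparc (-0.76), ndufaf6 (-0.67), fbxo2 (-0.65) and rpe (-0.48). In 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, as many genes passed; the highest other split gave 0, and 10 splits are too few for a share under 0.05.

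For the 166 genes called in opposite directions, the other probes of 91 genes argue against opposite actions of mITP: their median difference was 0.02 against 1.00 for the called probes, a ratio of 0.0182 (95% bootstrap interval -0.0135 to 0.0556), although they were far dimmer (median log2 intensity 8.04 against 13.12). A GT repeat was over-represented among the 166 (odds ratio 357, exact 95% interval 236 to 552), and across the 150 genes on such probes Cy5 was the brighter channel on all 6 arrays for 84.7%. Probes without the repeat gave a ratio of -0.0175 (-0.0969 to 0.0583) over 43 genes, so a dye effect of the probe is a candidate explanation there too. For the 1335 other genes called in the difference on probes without the repeat the ratio was 0.207 (0.170 to 0.244; 756 genes with another probe), against 0.634 (0.537 to 0.778) for genes called in the average, in which a dye effect cancels. How much of their difference comes from the dyes stays open, as genotype and dye orientation cannot be told apart and the other probes were dimmer (median log2 intensity 8.04 against 10.79).

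In the DMSO RNA of wild-type replicate 3, cyp1a stood 2.91 above the mean of the other 2 replicates on the log2 scale. Treated RNA mixed into this channel would need a share of 22% and would have raised cyp1c1, cyp1c2, ahrra and cyp1b1 as well. Their rise was a median of 0.125 of what that share would give, which argues against it, although cyp1b1 alone came near (0.77 against 0.97). A defect of 1 spot is excluded as the cause, as the 2 other cyp1a probes rose by 2.04 and 2.26, a median of 0.740 of the rise, and differed by at most 0.14 between replicates 1 and 2. AHR activity in these control embryos stays open, as 6 of 10 other AHR targets (60%, exact 95% interval 26.2% to 87.8%) were higher there than in both other replicates. Among the 6 were cyp1b1 (a rise of 0.77) and ahrra (0.56), but also ahrrb (0.11), which was not well above background in DMSO. cyp1c1 (-0.34) and tiparp (-0.24) were lower there. The 10 had been called higher with mITP against these same DMSO channels, which weakens the count as a test.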

How the results depend on the processing

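Leaving out probes with GT or CA repeats was chosen only after the result was seen; the other alternatives were not. Called values seldom changed sign, and calls were lost more often. Many named genes had been picked for the same sign on every array or for no overlap between genotypes. Leaving out an array or asking for a larger fold cannot turn the sign of such genes. The kept signs were thus in part fixed in advance and are no test of direction. Of 3557 values of named genes under an alternative, 2800 stayed on the same side of the threshold without a called value changing sign, 750 lost their call, 6 gained one and 1 called value changed sign. That one was eno1a in the difference, -0.179 with the mean of a gene's probes, where its 3 other probes oppose the one used. Where no cause is given below, the cause was not tested.

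Median centring in place of loess left 0 genes called in the wild-type response, 0 in the mutant response, 5 in the average and 0 in the difference. It leaves the trend of the ratio with brightness in place, and the median over tested genes then stood at -0.198 in the mutant response, -0.119 in the average and 0.112 in the difference. Under it the lists for NRF2 and p53 in the average (camera adjusted p = 0.572 and 0.912) and for liver in the difference (0.626) changed direction. Feature Extraction's processed intensities gave 678, 158, 31 and 815 genes in the same order. No background correction gave 2018 in the wild-type response. An offset of 16 gave 507 there and 894 in the difference. The mean of a gene's probes gave 158 in the mutant response and 921 in the difference. The 3 wild-type arrays alone gave 260, with fewer degrees of freedom. Array weights gave 473 in the mutant response and 3829 for the genotype difference. Median centring of intensities between arrays gave 72 for the genotype difference, with the median over genes at -0.125. Asking for at least 2-fold left 18, 4, 10, 98 and 87 genes in the 5 comparisons, by construction. Without the repeat probes 124 genes were called in the mutant response and the odds ratio for genes up in both was 10.85. The share of higher calls was 57.3% in the wild-type response but 67.7% with the authors' value table and 68.1% with processed intensities, 38.1% in the average but 52.0% with the value table, and 51.8% for the genotype difference but 18.1% with median centring and 32.4% with the DMSO channels alone. The DMSO channels alone called 1018 genes, of which 418 were also called in the main fit. DMSO RNA was in Cy3 in wild type and in Cy5 in mutants, so a dye effect of a probe stays in that comparison. The value table holds ratios only and gave no genotype difference, and no slide block could be fitted.

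Of the lists called by camera, 0 in each of the 5 comparisons passed with an estimated correlation. fry called 1 in the wild-type response, 0 in the mutant response, 1 in the average, 3 in the difference and 4 for the genotype difference. fry asks whether a list's own genes move 1 way, not whether they do so more than others. For genes up in both and down in both, the odds ratios at an unadjusted p under 0.05 were 0.440 and 0.462, on the other side of 1.

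The replicate numbers did not pair the samples. The deviations of same-numbered wild-type and mutant arrays correlated at -0.0420, 0.123 and 0.0367 for ratios and at -0.0551, -0.10 and 0.0471 for intensities, and not every array correlated best with its own number. With the replicate block, 757 genes were called in the wild-type response, 187 in the mutant response, 69 in the average, 1023 in the difference and 430 for the genotype difference. The odds ratio under this block was 17.1 for genes up in both and 4.66 for genes down in wild type and up in mutants, the latter no longer passing (1 gene).

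Leaving out 1 array gave 289 (without wild-type replicate 3) to 879 genes in the wild-type response, 36 (without mutant replicate 3) to 324 in the mutant response, 29 (without mutant replicate 3) to 94 in the average, 422 (without mutant replicate 3) to 1509 in the difference and 215 (without mutant replicate 1) to 745 for the genotype difference. Lists past camera then numbered 6 to 10, 2 to 4, 8 to 12, 4 to 7 and 8 to 13 in the same order. The odds ratios ran from 0 to 15.8 for genes up in both, 7.48 to 20.01 for down in both, 52.1 to 157 for up in wild type and down in mutants, and 0 to 16.8 for the reverse. Each such fit has 1 array fewer, which by itself lowers what can be called. Between 69.3% and 76.8% of gene spots per channel were well above background. A bound is given only for named genes dim on all 3 arrays of a group. Dim values, those behind a bound included, entered the fits as measured where their probe passed the filter.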

Other observations

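The split of hox genes by paralog group and the count of late tissues were chosen only after the result was seen; the regroupings and the tests on genotype differences were not.

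Some single genes that changed in the average of both genotypes belong to tissues whose lists did not pass. gfap, the intermediate filament of radial glia, fell by 0.31 on the log2 scale (limma adjusted p = 0.0189), and myod1, a regulator of muscle identity, by 0.24 (0.0450). In developing cartilage and bone, col10a1a, a collagen of hypertrophic cartilage and of bone, fell by 0.34 (0.0249) and barx1, a homeobox gene of the pharyngeal arches, by 0.22 (0.0476). Of leukocyte and inflammation genes, lect2l, a secreted chemotactic protein, fell by 0.40 (0.0118) and ctss2.1, a lysosomal protease, rose by 0.67 (0.0359). smtnl1, a smoothelin-like gene of contractile tissue, rose by 0.40 (0.0185) and mvp, the major vault protein, by 0.38 (0.0174). In mutants alone only gfap passed. Each had the same sign on all 6 arrays except ctss2.1 (-0.06 in mutant replicate 1), and each call was lost with median centring and with Feature Extraction's processed intensities.

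The hox genes called lower in the average all belonged to paralog groups 1 to 8, but not every gene of these groups fell. Of 24 measured genes of paralog groups 1 to 8, which are expressed from the hindbrain into the trunk, 13 were called lower by limma in the average. Of 23 in groups 9 to 13, of the posterior trunk, tail and fins, 0 were called lower and 1, hoxc13a, was higher (0.33). Beside those already named, hoxb8b (-0.66), hoxb6a (-0.65), hoxb1b (-0.49), hoxb8a (-0.48), hoxc5a (-0.47) and hoxa5a (-0.42) fell, chosen after their values were seen. Others of groups 1 to 8 were not called, among them hoxa2b (0.06), hoxb4a (-0.065), hoxd4a (-0.14), hoxc6b (0.087) and hoxb7a (0.011), also chosen after their values were seen. The median was -0.32 in wild type and -0.28 in mutants for groups 1 to 8, and 0.07 and 0.05 for groups 9 to 13.

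A hypothesis is that mITP lowered retinoic acid signalling. Retinoic acid is known to induce the anterior hox genes, part of which fell, and also cyp26a1 and dhrs3a, which fell too. The medians of the groups of hox genes differed by -0.365, but this split was made after the called genes had been seen and is no test of the hypothesis. Reporter lines or measured retinoic acid in embryos with and without mITP would test it. Slower development of treated embryos is another candidate explanation. It would lower the genes of late-appearing tissues together, and of 4 such lists 1 had a median under -0.1, photoreceptors at -0.15, with -0.07 for exocrine pancreas and gut, -0.00 for pigment cells and 0.01 for skeletal muscle. The photoreceptor median was -0.025 in wild type, where the list did not pass, and -0.27 in mutants. These values leave a delay open, in particular for the retina of mutants.

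Other splits of the arrays bear on how many calls grouping alone can give. For the average response, 2 of 32 regroupings of signs called as many genes as the real 84, so the count alone does not set the real signs apart from others. The other turns the signs of all mutant arrays, which makes it the difference in response itself, with the same 1533 genes. It holds differing responses of the genotypes as well as any dye effect, and these cannot be told apart. The highest of the rest called 7. For the wild-type response 1 of 4 regroupings, the real one with 1147, called as many (highest other 0), and for the mutant response 1 of 4, with 313 (highest other 1); 4 are too few for a share under 0.05. For the genotype difference it was 1 of 10 splits, with 780 (highest other 0), also too few.

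The genes that differed between the genotypes were crowded on the chromosome of ahr2. Within 10 Mb of the ahr2 probe 43 of 339 genes were called (12.7%, against 3.84% elsewhere; odds ratio 3.64, exact 95% interval 2.56 to 5.08), and among 25 chromosomes the odds ratio was highest for chromosome 22. The whole of chromosome 22 gave much the same share (12.2%, odds ratio 3.645, exact 95% interval 2.82 to 4.66), so the calls were not clearly denser near ahr2 than on the rest of it. Variants of the mutant line linked to the ahr2 allele may account for part of these calls, either by changing expression or by weakening a probe's match. The other probes of 361 called genes carried 0.269 of the called probes' difference (0.219 to 0.326), less than the 0.634 found for the average response, so hybridisation of single probes is a candidate explanation for much of the rest. A change in expression caused by the loss of ahr2 stays open, as does the slide, which cannot be told apart from the genotype.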
